A study of Homo sapiens with 14 samples.

How the data were processed

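Polyadenylated RNA was sequenced from 6 groups of H1 cells: undifferentiated hPSCs, kept in mTeSR Plus, and 5 stages of differentiation in the serum-free medium CDM2. Per the labels each step lasted 24 hours, and artery, primed and vein ECs were sorted for CD144 while the other groups were not. The factors added at each step are not given in the labels. There was 1 table per sample, 14 in all. The authors made the deposited estimated counts per transcript with kallisto against the human genome build hg38 (GRCh38), unscaled for sequencing depth. The deposited TPM values were made by the authors with kallisto from the same counts and the effective length of each transcript, so that they sum to the same total in every sample. The version of kallisto, its index, read trimming and the strand setting are not given in the sources used here, so values of antisense and overlapping genes are less certain.

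Each table held 188753 transcripts. Of these, 169754 were matched to a gene of GENCODE release 29 by transcript identifier, 158732 of them also by version, and 18999 had no match and were left out. The unmatched transcripts took 2.27% to 2.49% of a library's counts. Counts and TPM were summed to 35544 genes, and summed counts were rounded. Reads shared between close paralogs or repeated loci, such as LEFTY1 and LEFTY2 or HSPA1A and HSPA1B, were divided by the authors' estimation and are less certain per gene.

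The tables of hPSC replicates 1 and 2 had identical transcript lengths and effective lengths, TPM values within 4.97e-08 of each other, and counts that differed by more than 1 in 1 transcript, of EEF1A1. Over the transcripts of each pair with at least 20 counts, 59300 of them for this pair, chi-squared per degree of freedom was 5.665e-05 for this pair and 10.79 to 39.96 for the other pairs within groups. The tables were therefore treated as 1 library and averaged, which left 13 independent libraries, 2 of hPSCs, 3 of primitive streak and 2 of each other group. The plan written before the data were examined had counted 14 samples. Totals ran from 43352851 to 85941657 estimated counts per library, and mitochondrial transcripts took 3.27% to 5.29% of the counts.

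Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling (factors 0.8664 to 1.142), genes kept by filterByExpr with a minimum count of 10, and a quasi-likelihood fit of group means over all 13 libraries with 7 residual degrees of freedom. The fit tested 18382 genes in 7 comparisons of groups. P-values were two-sided and adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. The SE of a log2 fold change is its size divided by the root of the F statistic. TPM means are not scaled by TMM, so their ratio can differ from the fitted fold. For a gene with no count in a group, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts the ratio has an exact 95% binomial interval. The principal components and correlations used log2 CPM with a prior count of 1.

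Before the data were examined, 28 gene lists with 513 entries were fixed from textbook knowledge: pluripotency, primitive streak, definitive endoderm, neural ectoderm, paraxial mesoderm, lateral mesoderm, cardiac, epithelial, mesenchymal and EMT, targets of WNT, BMP, TGF-beta and NODAL, ERK and NOTCH, endothelial, artery, vein, lymphatic, hemogenic and blood, tip cell and VEGF response, mural mesenchyme, G1/S, G2/M, cholesterol synthesis, glycolysis and hypoxia, dissociation stress, inflammatory adhesion, and flow and maturation. Some genes are in several lists. The lists suited to each comparison were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini and Hochberg over the lists of the comparison. Member counts were also taken from p-values adjusted over the list alone.

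The rule for named genes was fixed at the same time. It took the 8 called genes with the largest rise and the 8 with the largest fall in the 3 comparisons between ECs, and 5 and 5 in the others, among genes with a mean of at least 10 TPM in the higher group and no overlap between the libraries of the groups compared. From each list it took up to 4 called members with the largest change and up to 2 members not called with the highest TPM. It also took 21 lineage genes in every comparison: POU5F1, NANOG, SOX2, TBXT, MIXL1, HAND1, FOXF1, KDR, ETV2, CDH5, PECAM1, SOX17, DLL4, CXCR4, NR2F2, APLNR, NRP2, FLT4, NT5E, DUSP6 and SPRY4. Some of these were left out of the text for length.

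The alternatives planned before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, effective-length offsets, only the 2 groups compared, the replicate number of the labels as a block, the adjusted p alone, each library left out in turn, and, for lists, an estimated correlation, the block and the rotation test fry. Keeping both copies of the hPSC library was added after the data were seen. The replicate numbers did not pair the libraries: across genes, deviations from the group mean correlated at -0.0368 to 0.0385 between libraries of the same number. The pipeline was tested on simulated counts with 200 changed genes per comparison: 3-fold and 6-fold changes were recovered in 100% of cases, 1.5-fold changes in 0 to 4.478%, and 1 to 4 unchanged genes were called. The changed genes were drawn from those with a mean CPM above 1, and all other genes had the same expected CPM in every group. Spread followed the fitted trend alone. Recovery was thus not tested for genes with fewer counts, for gene-specific spread or for the larger share of genes called in the data. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.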

Results

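Polyadenylated RNA was sequenced from H1 human pluripotent stem cells (hPSCs), an established embryonic stem cell line, and from 5 stages of a serum-free differentiation to endothelial cells (ECs). The stages were mid primitive streak (day 1), lateral mesoderm (day 2), artery ECs and primed ECs (both day 3, both made from lateral mesoderm) and vein ECs (day 4, made from primed ECs). The ECs were sorted for CD144, the surface protein encoded by CDH5, and the earlier stages were not sorted. There were 13 independent libraries, 3 of primitive streak and 2 of every other group, with 43352851 to 85941657 estimated counts each. A further hPSC table, replicate 2, held the same library as replicate 1 and was averaged with it. With 2 libraries per group, SDs and p-values measure only the spread between these libraries, which the labels do not describe as separate cultures, so the spread may be technical alone. Values below are group means in TPM, the transcript abundance scaled to length and depth, ± SD, with n = 3 for primitive streak and n = 2 for every other group, and log2 fold changes ± SE from the fit across 18382 genes. A gene was called at an adjusted p under 0.05 with a log2 fold change of at least 1 in size, and for every gene named for the size of its change the libraries of the groups compared did not overlap in TPM. For a gene list, the first value after the counts of its members is the list's adjusted p from the camera test, and where no value with an estimated correlation follows, the call of a called list held with it.

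Libraries of a group lay close together. Across genes, which are not independent replicates, the correlation of log expression was 0.9881 to 0.9928 within groups. It was 0.9653 to 0.9681 between artery and primed ECs, 0.9385 to 0.9414 between primed and vein ECs, and 0.9175 to 0.9214 between artery and vein ECs. The share of genes called ran from 14% for primed against artery ECs to 32.1% for primitive streak against hPSCs.

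**Figure D1:**
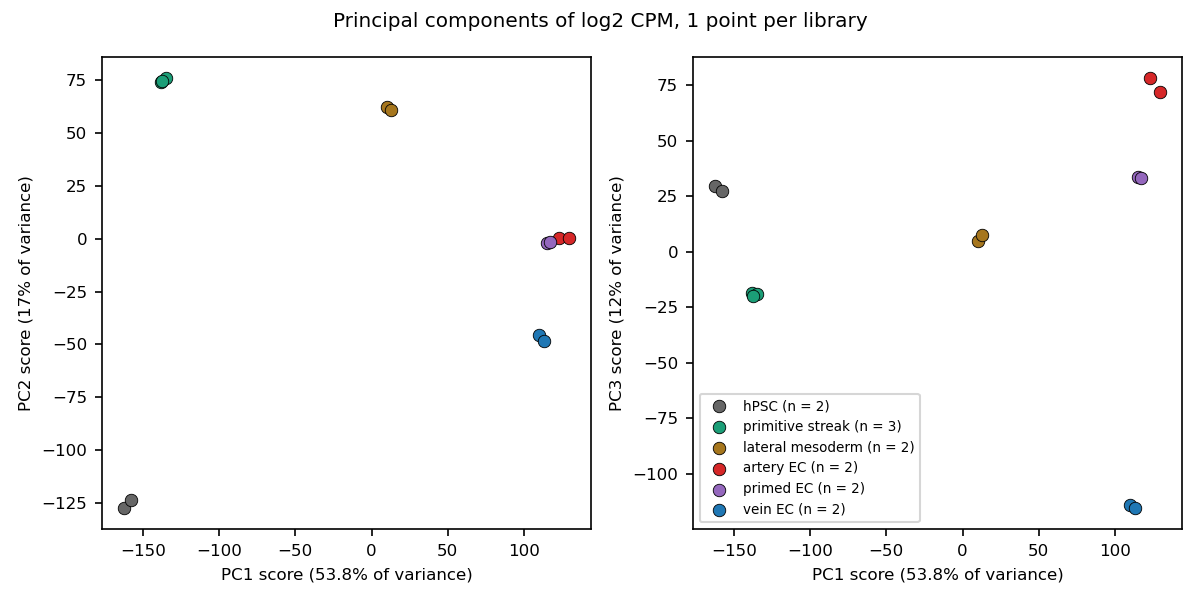
Scores of the 13 independent libraries on the leading principal components of log2 CPM, 1 point per library and 1 colour per group, with the share of variance on each axis. The first component (53.8% of the variance) runs from hPSCs to ECs, and the third (12.0%) holds artery ECs at 72.27 and 78.15, primed ECs at 33.10 and 33.56 and vein ECs at -114.0 and -115.3.

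The first comparison asked what changed as hPSCs became mid primitive streak, the population from which mesoderm and endoderm arise. TBXT (brachyury, ENSG00000164458, GRCh38 chromosome 6, 166157656 to 166168700, minus strand), which mesoderm formation requires, went from 0.200 ± 0.0823 to 809 ± 21.0 TPM (log2 fold change 11.94 ± 0.139, adjusted p 4.3e-17). MIXL1, another primitive-streak transcription factor, went from 1.16 ± 0.347 to 2339 ± 152 TPM (10.79 ± 0.157). SOX2, a pluripotency factor that is also neural, fell from 213.4 ± 9.72 to 0.362 ± 0.0595 TPM (-9.53 ± 0.131, adjusted p 7.4e-17), while POU5F1 (OCT4, ENSG00000204531, chromosome 6, 31164337 to 31180731, minus strand) stayed abundant at 1584 ± 58.0 against 3383 ± 425 TPM (-1.41 ± 0.111). Between them NANOG fell by 2.35 ± 0.0703 on the log2 scale. In all, 2726 genes were higher and 3182 lower in primitive streak.

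All 20 genes of the primitive-streak list were higher (list adjusted p 1.9e-75), among them NODAL (5.11 ± 0.127), the ligand that patterns the streak. MSGN1, a presomitic mesoderm factor, averaged 488.4 ± 4.58 TPM in primitive streak and had no count in hPSCs, so it was at least 3910-fold higher, taking 3 counts over the group as the floor. EVX1 had 1 to 3 counts in hPSCs and a ratio of 18300 (95% interval 5060 to 151000). Intervals and floors here and below cover counting error only. Of the 20 pluripotency genes, 13 were lower, 2 higher and 5 not called (1.2e-08). PRDM14 fell by 4.50 ± 0.146, whereas LIN28A (-0.81) and ZFP42 (-0.50) were not called. Of the 12 paraxial mesoderm genes, 9 were higher and 3 lower (2.5e-09), and of the 20 lateral mesoderm genes, 18 were higher (4.9e-36). FOXF1, a lateral plate factor with no count in hPSCs, was at least 2070-fold higher, and APLNR, the apelin receptor, went from 0.278 ± 0.0111 to 159.4 ± 3.18 TPM (8.80 ± 0.116).

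Signalling target lists moved in the same comparison. Of the 17 WNT targets, 15 were higher and none lower (1.4e-69), with the WNT inhibitor DKK1 at 2141 ± 100 against 0.857 ± 0.316 TPM (11.45 ± 0.146). Among the 16 BMP targets 14 were higher and 1 lower (3.4e-20), with MSX1 at 11.24 ± 0.193 and MSX2 at 8.88 ± 0.152. The 16 TGF-beta and NODAL targets split into 8 higher, 5 lower and 3 not called (1.3e-05), with CER1 at 6.20 and SKIL (0.24) not called. The 23 ERK targets split into 11 higher, 4 lower and 8 not called (0.00013; adjusted p = 0.099 with an estimated correlation). SPRY4 was higher by 2.08 ± 0.280 (adjusted p 7.9e-06). DUSP6 went the other way without a call, and was called lower under DESeq2 (-1.02) and with the size factors of DESeq2 in edgeR (-1.02).

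Of the 17 mesenchymal and EMT genes, 15 were higher and none lower (9.9e-24), with SNAI1, a repressor of E-cadherin, at 5.19 ± 0.106 and SNAI2 at 5.55 ± 0.154. The epithelial list was not called, with 4 genes higher, 3 lower and 10 not called (0.55). CLDN3 fell by 6.08 and CLDN4 by 3.93, EPCAM (-0.39) was not called, and KRT19 was higher (1.82). Lists not called were also definitive endoderm (6 higher, 3 lower, 6 not called; 0.06), neural ectoderm (4 higher, 2 lower, 4 not called; 0.7), G1/S (4 higher, 16 not called; 0.071) and G2/M (1 higher, 1 lower, 18 not called; 0.85). In the G2/M list the median and the mean of the log2 fold changes were above 0 while the direction of the test was downward. With a replicate block the definitive endoderm list had an adjusted p of 0.043. The counts of every list in this comparison were the same when adjusted over the list alone.

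The second comparison asked what changed as primitive streak became lateral mesoderm, the source of heart and vessels. Streak genes fell and endothelial genes appeared. TBXT fell from 809 ± 21.0 to 2.57 ± 0.118 TPM (-8.24 ± 0.106, adjusted p 6.7e-17) and MIXL1 fell by 9.55 ± 0.145. KDR (VEGF receptor 2, ENSG00000128052, chromosome 4, 55078259 to 55125595, minus strand) rose from 37.13 ± 2.38 to 1761 ± 19.4 TPM (5.51 ± 0.127, adjusted p 1.1e-14). TAL1, a factor of blood and endothelial progenitors, rose from 0.0601 ± 0.00456 to 159.9 ± 9.87 TPM (11.04 ± 0.111), and ETV2 (ENSG00000105672, chromosome 19, 35641745 to 35644871, plus strand), which starts the endothelial programme, rose to 144.5 ± 13 TPM (7.37 ± 0.168), or 6.74 with effective-length offsets. Counts over all genes were 2983 higher and 2451 lower.

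In the endothelial list 26 of 28 genes were higher and none lower (3.3e-78), including FLI1 (9.49 ± 0.126), PLVAP (8.94) and CDH5 (ENSG00000179776, chromosome 16, 66366622 to 66404786, plus strand), at 45.25 ± 5.29 against 0.309 ± 0.101 TPM (7.37 ± 0.140). HHEX, a factor of early endothelium and liver, reached 202.1 ± 7.15 TPM (10.20 ± 0.139). The vein factor NR2F2 (COUP-TFII, ENSG00000185551, chromosome 15, 96325938 to 96340263, plus strand) went from 0.0864 ± 0.0309 to 5.34 ± 0.435 TPM (5.47 ± 0.218). The lateral mesoderm list had 10 genes higher, 4 lower and 6 not called (0.037; adjusted p = 0.23 with an estimated correlation, 0.18 with a replicate block). HAND1 was higher by 1.30 ± 0.0693, HAND2 by 6.83, FOXF1 fell by 1.51 and GATA6 (-0.25) was not called. The cardiac list had 5 genes higher, 1 lower and 9 not called (0.0082; adjusted p = 0.18 with an estimated correlation, 0.12 with a replicate block). NKX2-5, a heart-field factor, reached 188.9 ± 1.78 TPM (5.41 ± 0.125), TBX20 rose by 4.59 on the log2 scale, and the heart muscle genes ACTC1 (-0.40) and MYL7 (0.71) were not called.

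Of the 20 primitive-streak genes, 16 were lower and 2 higher (2.2e-35), and of the 20 pluripotency genes, 15 were lower and 2 higher (5.9e-08), with POU5F1 at 226.8 ± 6.93 TPM (-2.88 ± 0.127). The paraxial list had 7 genes lower, 2 higher and 3 not called (1.3e-07), and TBX6, which specifies paraxial mesoderm, fell by 4.95. Epithelial genes were lower in 12 of 17 cases and higher in 2 (3.9e-12), with the splicing regulator ESRP1 at -4.29 and RAB25 at -4.39. Mesenchymal genes were higher in 11 of 17 cases and lower in 1 (6.8e-07), with VIM (vimentin) at 3927 ± 158 against 820.5 ± 10.3 TPM and FN1 (fibronectin) at 2.90.

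WNT targets were lower in 16 of 17 cases and higher in none (2.9e-44), with DKK1 at 4.25 ± 0.0819 against 2141 ± 100 TPM (-9.09 ± 0.125). TGF-beta and NODAL targets were lower in 11 of 16 cases and higher in 4 (1.5e-05), with CER1 at -6.94 and TGFBI at 5.75. BMP targets went both ways and the list was not called (6 higher, 5 lower, 5 not called; 0.44), with SMAD9 at 2.96, DLX5 at -3.12 and ID1 (-0.02) not called. ERK targets were higher in 13 of 23 cases and lower in 2 (1.5e-05; adjusted p = 0.074 with an estimated correlation). The ERK phosphatase DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271, minus strand) rose from 59.5 ± 5.16 to 604.8 ± 9.97 TPM (3.27 ± 0.204). Definitive endoderm (4 higher, 5 lower, 6 not called; 0.44), G1/S (1 higher, 2 lower, 17 not called; 0.073) and G2/M (1 lower, 19 not called; 0.073) were not called. With a replicate block, both cell-cycle lists had an adjusted p of 0.035. Adjusted over the list alone, every list of this comparison had the same counts.

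The third comparison set artery ECs against the lateral mesoderm they were made from and asked which genes marked the arterial route. The arterial genes CXCR4 and DLL4 were higher in artery ECs. ESM1 (ENSG00000164283, chromosome 5, 54977864 to 55022671, minus strand), a secreted product of VEGF-stimulated tip cells, went from 0.301 ± 0.0687 to 5265 ± 446 TPM (14.16 ± 0.184, adjusted p 4.0e-16). CXCR4 (ENSG00000121966, chromosome 2, 136114349 to 136118165, minus strand), a chemokine receptor of arterial and tip cells, went from 15.44 ± 2.46 to 1013 ± 3.45 TPM (6.16 ± 0.123, adjusted p 6.0e-15), and the NOTCH ligand DLL4 (ENSG00000128917, chromosome 15, 40929333 to 40939073, plus strand) from 2.23 ± 0.137 to 398.9 ± 26.5 TPM (7.59 ± 0.118). NR2F2 fell from 5.34 ± 0.435 to 0.148 ± 0.0225 TPM (-5.20 ± 0.247, adjusted p 5.8e-11). The comparison called 2467 genes higher and 2689 lower, and because only the ECs were sorted, the sort and the differentiation step changed together.

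Endothelial genes were higher in 20 of 28 cases and lower in 2 (6.8e-25), with CDH5 at 858.3 ± 74.8 TPM (4.38 ± 0.119), CD34 at 5.98 and ROBO4 at 7.36. KDR (-0.30) and FLT1 (0.56) were not called, and ETV2 fell by 6.16. The artery list had 19 genes higher, 6 lower and 1 not called (3.1e-22), including IGFBP3 (6.91), SEMA3G (6.64) and SOX17 (ENSG00000164736, chromosome 8, 54457935 to 54460888, plus strand), at 474.8 ± 25.6 against 23.67 ± 3.43 TPM. The vein list had 10 genes lower and 5 higher (0.034; adjusted p = 0.26 with an estimated correlation, 0.063 with a replicate block), with APLNR (ENSG00000134817, chromosome 11, 57233577 to 57237314, minus strand) falling by 5.44 to 16.03 ± 2.91 TPM and VWF higher by 4.87. NOTCH targets were higher in 7 of 13 cases and lower in 4 (0.00011), with HEY1 at 941.5 ± 52.4 TPM (3.69 ± 0.0806) and NRARP at 4.89. The hemogenic and blood list had 9 genes lower and 3 higher (0.0044; adjusted p = 0.12 with an estimated correlation), with MYB at -3.69 and IKZF1 at -4.76.

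All but 1 of the 20 lateral mesoderm genes were lower and none higher (2.3e-26), with HAND1 (ENSG00000113196, chromosome 5, 154474972 to 154478264, minus strand) at -7.25 and PRRX1 at -5.99. The mural list, markers of vessel wall and stromal cells, had 10 of 18 genes lower and 2 higher (0.00028), with DES at -4.70. Cardiac genes were lower in 8 of 15 cases and higher in 1 (0.0044; adjusted p = 0.19 with an estimated correlation), with MYL7 at -5.49. The mesenchymal and EMT list was not called (8 lower, 1 higher, 8 not called; 0.055), with SNAI1 at -2.43 and ZEB1 at 2.61. BMP targets were lower in 14 of 16 cases and higher in none (7.8e-22), with ID2 at -6.49 and SMAD9 at -4.69. WNT targets were lower in 14 of 17 cases and higher in 1 (4.0e-09), with LGR5 at -5.03. ERK targets were lower in 10 of 23 cases and higher in 2 (0.0044; adjusted p = 0.2 with an estimated correlation), with SPRY2 at -2.42 and DUSP6 at -1.26 ± 0.220. TGF-beta and NODAL targets were not called as a list (7 higher, 3 lower, 6 not called; 0.052), though PMEPA1 rose by 4.19 and CER1 by 4.11.

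G1/S genes were lower in 13 of 20 cases and higher in none (3.8e-07), with CCNE1 (cyclin E1) at -2.15 and CDC6 at -1.88. The G2/M list had 1 gene lower and 19 not called (0.019; adjusted p = 0.23 with an estimated correlation), with CDK1 at -1.17. Dissociation stress genes were not called as a list (5 higher, 4 lower, 9 not called; 0.8), with JUN at 1.80 and NFKBIA at -2.56. The same member counts came from p-values adjusted over the list alone for all lists of this comparison.

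The fourth comparison set primed ECs, the cells labelled as precursors of vein ECs, against the same lateral mesoderm. Endothelial genes rose here as well, while the vein factor NR2F2 stayed at its lateral mesoderm level, at 5.24 ± 0.611 against 5.34 ± 0.435 TPM (0.07, adjusted p 0.71, not called). CDH5 rose to 554.2 ± 1.57 TPM (3.64 ± 0.115, adjusted p 8.0e-13) and ESM1 to 213.2 ± 8.98 TPM (9.39 ± 0.170). APLNR, at 497.5 ± 2.04 TPM, was not called (-0.59), CXCR4 fell by 1.82 ± 0.120, and NT5E (CD73, ENSG00000135318, chromosome 6, 85449584 to 85495791, plus strand) rose by 3.19 ± 0.122 on the log2 scale. The calls numbered 1940 higher and 2512 lower, again with the sort and the step changing together.

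Of the 28 endothelial genes, 19 were higher and 1 lower (1.4e-28), including CD34 (6.40), CLDN5 (6.99) and PECAM1 (4.06). The artery list was mixed, with 12 genes higher, 10 lower and 4 not called (0.0082, upward; 0.24 with a replicate block). DLL4 reached 24.76 ± 0.746 TPM (3.45), SOX17 reached 208.1 ± 5.56 TPM (3.14) and JAG2 rose by 5.90. The vein list had 6 genes higher, 1 lower and 12 not called (0.00012; 0.17 with a replicate block), among them VWF at 4.42 and EMCN at 6.16, or 4.26 with effective-length offsets. NRP2 (0.09) was not called. CYP1A1, a cytochrome P450, was among the largest changes, at 57.6 ± 2.51 against 0.237 TPM (7.95 ± 0.176).

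All 20 lateral mesoderm genes were lower (1.3e-33), with HAND1 at -6.14. Cardiac genes were lower in 8 of 15 cases and higher in 3 (0.01; adjusted p = 0.23 with an estimated correlation, 0.054 with a replicate block), with NKX2-5 at -5.24. The mural list had 8 of 18 genes lower and none higher (0.007), with PDGFRB at -3.29, and the mesenchymal list had 9 of 17 lower and 1 higher (4.8e-05), with CDH11 at -2.57. BMP targets were lower in 13 of 16 cases and higher in none (5.5e-20), with SMAD7 at -3.84, while ID1 (-0.11) and ID3 (-0.56) were not called. TGF-beta and NODAL targets were lower in 9 of 16 cases and higher in 2 (7.1e-05). WNT targets were lower in 12 of 17 cases and higher in 2 (1.7e-10), with LGR5 at -5.57 and cyclin D1 (CCND1) higher, at 770.2 ± 4.46 against 131.4 ± 2.35 TPM. ERK targets were lower in 10 of 23 cases and higher in 4 (0.038; adjusted p = 0.34 with an estimated correlation), with DUSP6 at -1.67 ± 0.223.

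The hemogenic and blood list was balanced at 6 higher and 6 lower (0.95), with VAV1 at 5.22, or 4.52 with effective-length offsets, and GATA2 at -2.74. Its median was below 0 while its mean and test were above. The NOTCH target list had 5 genes higher and 4 lower (0.75), with HES1 at -4.94 and NRARP at 3.36, and its median and mean were below 0 while its test was above. None of the 20 G1/S genes was called (0.95), and there the mean was above 0 while the median and test were below. The G2/M list had 2 genes higher and 18 not called (0.014; adjusted p = 0.26 with an estimated correlation), with BIRC5 at 1.07 and UBE2C (0.13) not called. Stress genes were not called as a list (2 higher, 4 lower, 12 not called; 0.92), with JUN at 1.99 and EGR1 at -1.28. Each list of this comparison gave the same counts adjusted over the list alone.

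**Figure D2:**
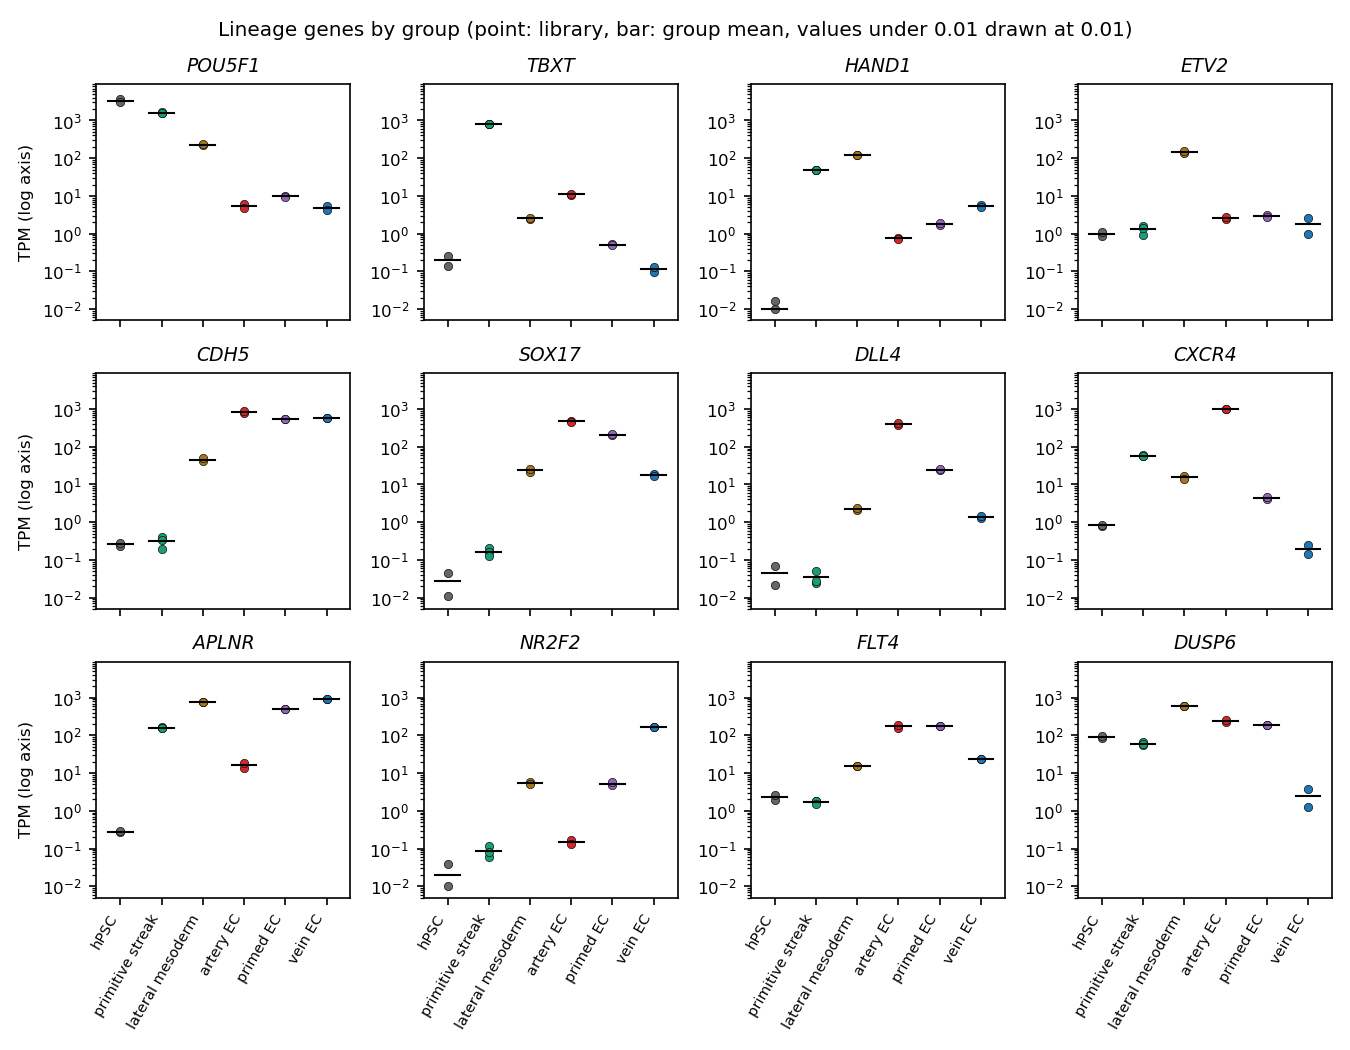
Expression of 12 lineage genes in TPM on a log axis, 1 panel per gene and 1 position per group, with a point per library and a bar at the group mean (values under 0.01 are drawn at 0.01). NR2F2 is near 5 TPM in lateral mesoderm and primed ECs (means 5.34 and 5.24), 0.148 TPM in artery ECs and 166.9 TPM in vein ECs, and CXCR4 peaks in artery ECs at 1013 TPM.

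The fifth comparison set primed against artery ECs, which were made from the same lateral mesoderm, harvested on the same day and sorted the same way. It asked how the route toward vein differed from the route toward artery at that time. CXCR4 was 4.41 ± 0.432 TPM in primed and 1013 ± 3.45 TPM in artery ECs (-7.97 ± 0.136, adjusted p 2.1e-14). NR2F2 was 5.24 ± 0.611 against 0.148 ± 0.0225 TPM (5.27 ± 0.244, adjusted p 1.8e-10) and APLNR 497.5 ± 2.04 against 16.03 ± 2.91 TPM (4.85 ± 0.0863). DLL4 was lower in primed ECs, at 24.76 ± 0.746 against 398.9 ± 26.5 TPM (-4.14 ± 0.0968), while the pan-endothelial genes CDH5 (-0.74), PECAM1 (-0.85) and KDR (-0.04) were not called. This was the smallest set of changes among the 7 comparisons, with 1205 genes higher and 1372 lower.

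Vein genes were higher in 13 of 19 cases and lower in none (1.0e-21). NT5E was 17.14 ± 1.62 against 0.976 ± 0.131 TPM (4.22 ± 0.136), EMCN was higher by 2.96 on the log2 scale, and FLT4 (-0.09) and TEK (0.30) were not called. Artery genes were lower in 15 of 26 cases and higher in 1 (4.1e-36), with GJA4 at -4.73, HEY2 at -2.46 and SOX17 at -1.31. The tip-cell and VEGF response list had 14 of 20 genes lower and 2 higher (2.7e-46), with ESM1 at 213.2 ± 8.98 against 5265 ± 446 TPM (-4.77 ± 0.114), ANGPT2 at -4.66 and PGF at -5.70. NOTCH targets were lower in 7 of 13 cases and higher in none (7.8e-12), with HES4 at -4.39 and HES1 at -2.34. These lists share genes such as DLL4 and CXCR4. The endothelial list was not called (2 higher, 5 lower, 21 not called; 0.17), with ICAM2 at 1.53 and SOX18 at -1.57.

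The ERK target list was not called between these groups (7 higher, 2 lower, 14 not called; 0.075), and its median was below 0 while its mean and test were above. DUSP6 (-0.42, adjusted p 0.14) was not called, SPRY4 fell by 1.60 ± 0.287 and EGR3 was higher by 2.08. TGF-beta and NODAL targets were lower in 12 of 16 cases and higher in 1 (4.4e-20), with PMEPA1 at -4.20, CER1 at -4.75 and the NODAL co-receptor TDGF1 at -3.72. BMP targets were higher in 5 of 16 cases and lower in 1 (0.0015), with ID1 at 313.3 against 40.52 TPM (2.79 ± 0.144), ID2 at 2.96 and SMAD7 at -1.69. WNT targets were not called as a list (3 higher, 1 lower, 13 not called; 0.42), with SP5 at 1.95. The hemogenic and blood list had 10 of 17 genes higher and 1 lower (3.3e-07), with SPI1 (PU.1) at 3.77 and IKZF1 at 3.22.

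Both cell-cycle lists were higher in primed ECs. Among G1/S genes 13 of 20 were higher and none lower (6.3e-16), with CCNE1 at 1.74 and GINS2 at 1.55, and among G2/M genes 9 of 20 were higher and none lower (4.3e-13), with CDK1 at 1.32 and TOP2A at 1.27. The cholesterol synthesis list had 1 gene higher and 20 not called (0.015; adjusted p = 0.45 with an estimated correlation). The glycolysis and hypoxia list had 2 genes higher, 2 lower and 18 not called (0.015; adjusted p = 0.28 with an estimated correlation), with ENO2 at 2.12 and SLC2A1 at -1.47. The flow and maturation list had 3 genes higher, 2 lower and 9 not called (0.028; adjusted p = 0.17 with an estimated correlation, 0.31 with a replicate block), with CAV1 at 4.16 and KLF4 at -1.76.

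Lists not called were lymphatic (1 higher, 3 lower, 6 not called; 0.57), lateral mesoderm (4 higher, 16 not called; 0.47), mural (3 higher, 2 lower, 13 not called; 0.075), stress (4 higher, 5 lower, 9 not called; 1) and inflammatory adhesion (6 higher, 1 lower, 4 not called; 0.075, or 0.031 with a replicate block). FOXC2, a lymphatic valve factor, was at -2.15 and SOCS3 at -2.43. ICAM1, at -2.21, was the 1 inflammatory adhesion gene called lower, against 6 called higher. The mural gene CSPG4 was at -1.68 and ACTA2 (not called) at -0.08. For lateral mesoderm the median was below 0 while mean and test were above, and for stress the median and mean were below 0 while the test was above. The lymphatic counts were 2 higher and 3 lower adjusted over the list alone, and the other lists had the same counts either way. Among the largest changes were SOST, a secreted WNT and BMP antagonist (6.62 ± 0.143), GRAP2 (4.46), and, lower, CHST1 (-6.60), KLHDC8A (-6.46) and GBX2 (-6.00).

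**Figure D3:**
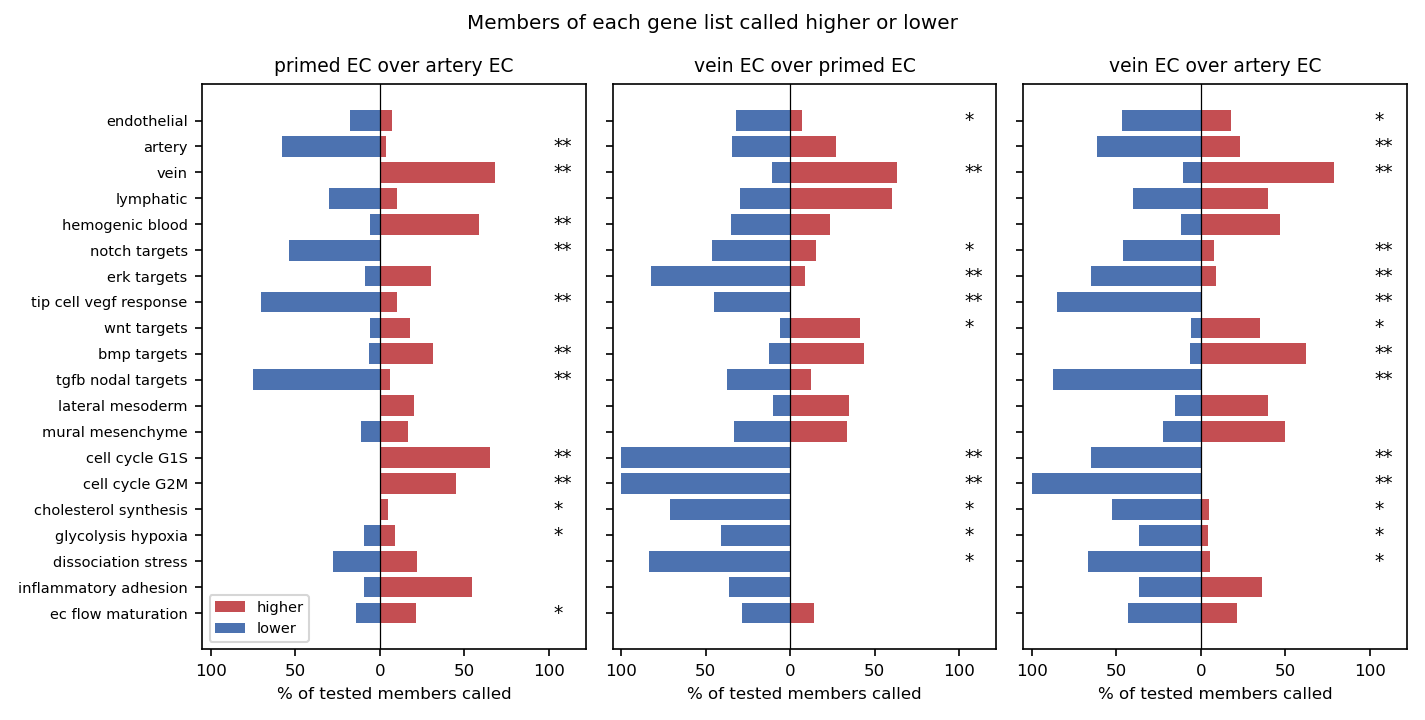
Percent of the tested members of 20 gene lists that were called higher (red, to the right) or lower (blue, to the left) in 3 comparisons of EC groups, 1 panel per comparison, with * for a list past its test and ** where the call also held with an estimated correlation. Of 19 vein genes, 13, 12 and 15 were higher in the respective panels, and all 40 cell-cycle genes were lower in vein than in primed ECs.

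The sixth comparison addressed the step from primed to vein ECs, for which the series asks about inhibition of VEGF and ERK signalling. Vein ECs were harvested a day later, so the step and the added day changed together. NR2F2 rose from 5.24 ± 0.611 to 166.9 ± 2.81 TPM (4.76 ± 0.141, adjusted p 4.1e-13). STAB2 (ENSG00000136011, chromosome 12, 103587273 to 103766727, plus strand), a hyaluronan scavenger receptor of sinusoidal endothelium, rose from 0.114 ± 0.0854 to 259.0 ± 9.74 TPM (12.22 ± 0.205, or 11.36 with effective-length offsets). ERK targets fell, with ETV4 at 1.31 ± 0.428 against 105.8 ± 3.80 TPM (-6.70 ± 0.133, adjusted p 1.1e-14), and proliferation genes fell, with MKI67 at 5.46 ± 0.0697 against 69.36 ± 2.06 TPM (-3.79 ± 0.202). The comparison called 3038 genes higher and 2314 lower.

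Of the 23 ERK targets, 19 were lower, 2 higher and 2 not called (2.8e-25). DUSP6 averaged 2.50 ± 1.78 against 192.6 ± 0.156 TPM (-6.62 ± 0.299, adjusted p 4.2e-11), with -7.80 without vein EC replicate 1 and -5.98 without vein EC replicate 2. SPRY4 (ENSG00000187678, chromosome 5, 142310427 to 142326455, minus strand), a feedback inhibitor of the pathway, averaged 1.30 ± 1.22 TPM in vein ECs (-6.78 ± 0.389), with -8.63 and -6.00 without those libraries in turn. The not-called members were PHLDA1 (0.38) and MYC (-0.36). Of the 19 vein genes, 12 were higher, 2 lower and 5 not called (2.1e-16), with NT5E at 150.9 ± 3.02 TPM (3.06 ± 0.106) and NRP2 at 1.06. FLRT2 rose to 324 ± 1.02 TPM (4.74 ± 0.0953, or 5.67 with effective-length offsets). FLT4 (VEGF receptor 3) was a vein-list gene that fell, by 3.08, and APLNR (0.70) and EMCN (0.87) were not called. The tip-cell list had 9 of 20 genes lower and none higher (1.1e-09), with ESM1 at 10.12 ± 0.538 TPM (-4.69), APLN at -5.64 and CXCR4 at -4.67.

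**Figure D4:**
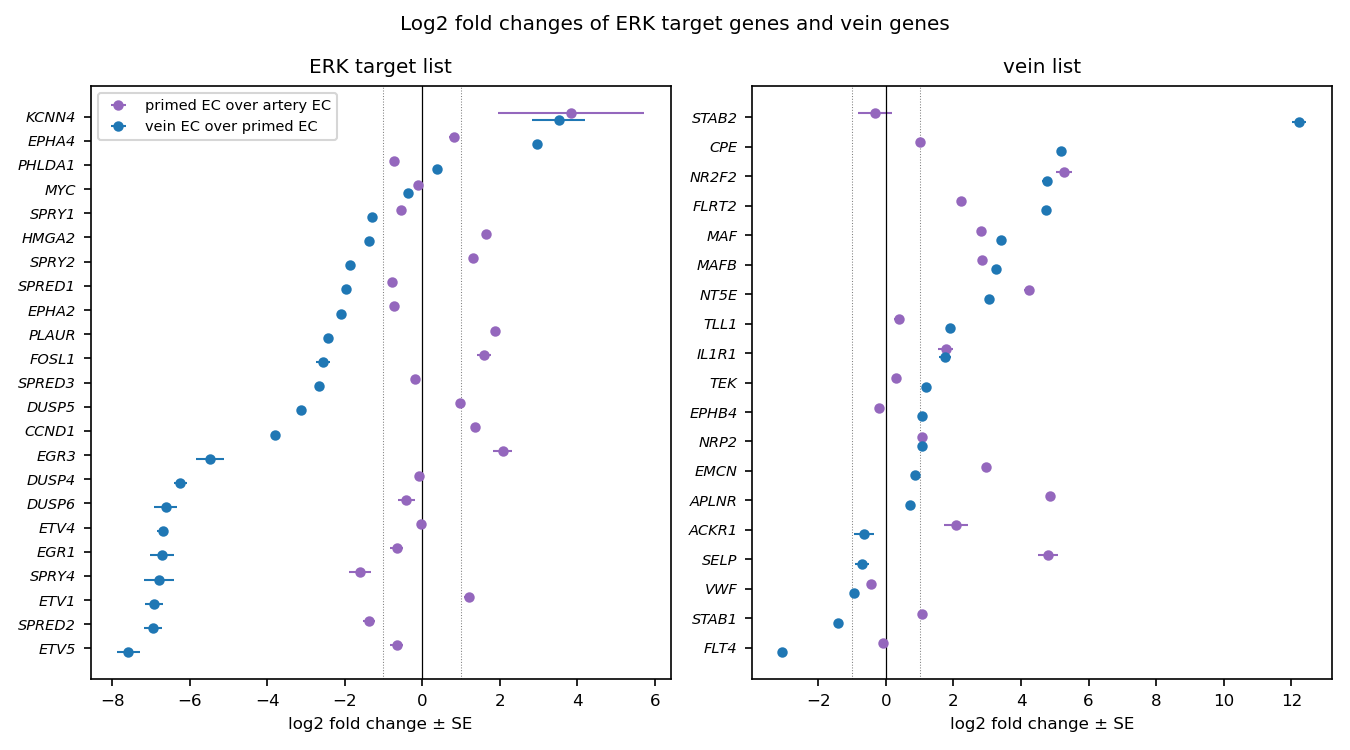
Log2 fold change ± SE of 23 ERK target genes and 19 vein genes for primed over artery ECs (purple) and vein over primed ECs (blue), with dotted lines at -1 and 1. In vein over primed ECs 19 ERK targets were lower and 2 higher, and 12 vein genes were higher and 2 lower. In primed over artery ECs 7 ERK targets were higher and 2 lower, and 13 vein genes were higher and none lower.

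Artery genes went both ways in this step and the list was not called (7 higher, 9 lower, 10 not called; 0.068). SOX17 fell from 208.1 ± 5.56 to 17.94 ± 0.850 TPM (-3.73 ± 0.119), DLL4 by 4.40 ± 0.112, TMEM100 was higher by 2.55, and EFNB2 (0.45) was not called. NOTCH targets were lower in 6 of 13 cases and higher in 2 (0.012; adjusted p = 0.11 with an estimated correlation, 0.2 with a replicate block), with HEY1 at 5.21 ± 0.0986 against 205.4 ± 0.400 TPM (-5.54 ± 0.0924) and DTX1 at 3.11. The endothelial list had 9 genes lower, 2 higher and 17 not called (0.0029; adjusted p = 0.18 with an estimated correlation), with PLVAP at -4.19, ROBO4 at -4.22 and CLDN5 at 2.73. CDH5 (-0.09), PECAM1 (0.40) and KDR (0.48) were not called. The lymphatic list was not called (6 higher, 3 lower, 1 not called; 0.1), with LYVE1 at 2.02 and FLT4 lower.

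All 20 G1/S genes (1.4e-31) and all 20 G2/M genes (2.9e-44) were lower in vein ECs, with CDC45 at -4.30 ± 0.0902, MCM10 at -4.58 ± 0.106, UBE2C at -4.09 and AURKB at -3.73. Cholesterol synthesis genes were lower in 15 of 21 cases and higher in none (1.2e-09; adjusted p = 0.12 with an estimated correlation), with IDI1 at -1.88. Glycolysis and hypoxia genes were lower in 9 of 22 cases and higher in none (1.2e-06; adjusted p = 0.095 with an estimated correlation), with LDHA at -2.19 and PFKP at -2.69, while GAPDH (-0.23) was not called. Dissociation stress genes were lower in 15 of 18 cases and higher in none (6.3e-12; adjusted p = 0.09 with an estimated correlation), with JUN at -3.62 ± 0.0788. EGR1 is the 1 tested gene that the stress and ERK lists share.

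WNT targets were higher in 7 of 17 cases and lower in 1 (0.041; adjusted p = 0.17 with an estimated correlation, 0.16 with a replicate block), with TNFRSF19 at 5.66, NKD1 at 2.02 and APCDD1 at -1.73. The BMP target list was not called (7 higher, 2 lower, 7 not called; 0.068, or 0.018 with a replicate block), with NOG at 3.99 and SMAD6 at -4.12. Also not called were TGF-beta and NODAL targets (2 higher, 6 lower, 8 not called; 0.14), hemogenic and blood genes (4 higher, 6 lower, 7 not called; 0.16), lateral mesoderm (7 higher, 2 lower, 11 not called; 0.094), mural markers (6 higher, 6 lower, 6 not called; 0.37), inflammatory adhesion (4 lower, 7 not called; 0.1) and flow and maturation (2 higher, 4 lower, 8 not called; 0.12). GFI1B was at -3.84, PRRX1 at 3.91, SELE at -4.36, KLF2 at -2.03 and NOS3 at -2.08. The mural list held LUM at 4.70, COL3A1 at 3.88 and THY1 at -4.04. Adjustment over the list alone left every member count of this comparison the same. Large changes outside these lists included CPE, a peptide-processing carboxypeptidase, at 261.1 ± 5.60 against 6.51 ± 0.0569 TPM (5.19 ± 0.0816), and IGF1 (ENSG00000017427, chromosome 12, 102395874 to 102481744, minus strand), a growth factor, at 89.89 ± 0.782 against 0.373 TPM (8.33 ± 0.162). IFI44 had no count in primed ECs and was at least 196-fold higher.

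The seventh comparison set the endpoints, vein and artery ECs, against each other and asked how far apart they were. It carries the added day of the vein ECs, and its libraries also serve the previous comparisons. CXCR4 was 0.194 ± 0.0740 TPM in vein and 1013 ± 3.45 TPM in artery ECs (-12.64 ± 0.186, adjusted p 5.3e-16), and NR2F2 166.9 ± 2.81 against 0.148 ± 0.0225 TPM (10.03 ± 0.216, adjusted p 8.6e-15). DLL4 was 1.40 ± 0.109 against 398.9 ± 26.5 TPM (-8.54 ± 0.124, adjusted p 5.3e-16), APLNR 938.7 ± 17.5 against 16.03 ± 2.91 TPM (5.55 ± 0.0891), and NRP2, a receptor of venous and lymphatic endothelium, 1020 ± 44.4 against 162.8 ± 37.1 TPM (2.12). There were 3027 genes higher and 2723 lower.

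Vein genes were higher in 15 of 19 cases and lower in 2 (9.2e-32), with NT5E at 7.28 ± 0.142 and EMCN at 3.83, FLT4 at -3.17, and EPHB4 (0.86) and STAB1 (-0.34) not called. Artery genes were lower in 16 of 26 cases and higher in 6 (7.9e-16), with HEY1 at -7.84, IGFBP3 at -6.95 and SOX17 at -5.04, and JAG2 (0.36) not called. Tip-cell genes were lower in 17 of 20 cases and higher in none (1.9e-34), with ESM1 at -9.46 ± 0.142 and ANGPT2 at -9.33. NOTCH targets were lower in 6 of 13 cases and higher in 1 (1.4e-07; 0.053 with a replicate block), with HES4 at -5.63 and HES1 at -5.51. ERK targets were lower in 15 of 23 cases and higher in 2 (7.9e-16). DUSP6 was at -7.03 ± 0.303, with -8.21 and -6.40 without vein EC replicates 1 and 2 in turn, and PHLDA1 (-0.33) was not called. The endothelial list had 13 genes lower, 5 higher and 10 not called (0.00072; adjusted p = 0.16 with an estimated correlation), with SOX18 at -3.62, PLVAP at -5.40 and CDH5 (-0.83) not called.

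TGF-beta and NODAL targets were lower in 14 of 16 cases and higher in none (2.9e-11), with PMEPA1 at -4.86 and TDGF1 at -4.55. BMP targets were higher in 10 of 16 cases and lower in 1 (0.00067), with ID2 at 4.50, NOG at 4.86 and SMAD6 at -3.27. WNT targets were higher in 6 of 17 cases and lower in 1 (0.014; adjusted p = 0.06 with an estimated correlation), with NKD1 at 2.92, and adjusted over the list alone 5 were higher and 1 lower. G1/S genes were lower in 13 of 20 cases and higher in none (1.4e-09), with MCM7 at -2.46 and PCNA (-0.57) not called, and all 20 G2/M genes were lower (3.0e-19), with UBE2C at -3.61. Cholesterol synthesis had 11 genes lower and 1 higher (9.2e-05; adjusted p = 0.21 with an estimated correlation). Glycolysis and hypoxia had 8 genes lower and 1 higher (0.0053; adjusted p = 0.21 with an estimated correlation), with SLC2A1 at -2.13 and ENO2 at 3.01. Stress genes were lower in 12 of 18 cases and higher in 1 (5.9e-09; adjusted p = 0.11 with an estimated correlation), with SOCS3 at -4.87.

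Lists not called were hemogenic and blood (8 higher, 2 lower, 7 not called; 0.066, or 0.048 with a replicate block), lymphatic (4 higher, 4 lower, 2 not called; 0.27), lateral mesoderm (8 higher, 3 lower, 9 not called; 0.066), mural (9 higher, 4 lower, 5 not called; 0.095), inflammatory adhesion (4 higher, 4 lower, 3 not called; 0.8) and flow and maturation (3 higher, 6 lower, 5 not called; 0.96). In the last 2 lists named, the test was downward, while the median of inflammatory adhesion and the median and mean of flow and maturation were above 0. RUNX1 was at 3.00, LYVE1 at 3.06, FOXC2 at -3.94, PRRX1 at 7.15, ICAM1 at -2.63, KLF2 at -3.04 and CAV1 at 4.60. In the mural list COL1A2 (ENSG00000164692, chromosome 7, 94394561 to 94431232, plus strand), a collagen chain, was 838.2 ± 1.69 against 10.22 ± 1.70 TPM (6.13 ± 0.110). Apart from the WNT targets, the counts adjusted over the list alone were the same in this comparison. CRYBA4, with no count in artery ECs, was at least 854-fold higher in vein ECs.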

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

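The comparison of lateral mesoderm with each EC branch was planned, and the search among named genes for opposite moves in the branches was chosen after the data were seen. No technical or biological explanation was tested for the results in this part.

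CXCR4 rose from lateral mesoderm to artery ECs (log2 fold change 6.16) and fell to primed ECs (-1.82), and the test of the difference between the branches gave -7.97 ± 0.136 (SE, adjusted p 2.1e-14, 2 libraries per group, no overlap in TPM). NT5E moved the other way, at -1.04 in artery ECs and 3.19 in primed ECs, with a difference of 4.22 ± 0.136 (adjusted p 3.3e-12). Its fall in artery ECs lay near the threshold and was not called with effective-length offsets (-0.98), without artery EC replicate 1 (-0.89) or without lateral mesoderm replicate 2 (-0.91). TBXT was higher in artery ECs (2.09, to 10.9 ± 0.268 TPM) and lower in primed ECs (-2.27, to 0.504 ± 0.0216 TPM) than in lateral mesoderm (2.57 ± 0.118 TPM), with a difference of -4.36 ± 0.122 (adjusted p 7.9e-13).

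Transcripts without a gene in the annotation took up to 2.49% of a library's estimated counts, in hPSC replicate 1, and at least 2.27%. No comparison used them.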

How the results depend on the processing

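All alternatives were planned except keeping both copies of the hPSC library, which was chosen after seeing the data. Under DESeq2, its size factors in edgeR, no low-count filter, effective-length offsets, only the 2 groups compared, the replicate block and both hPSC copies, every count of genes higher or lower stayed within 1.5 times its value in the report. For primitive streak against hPSCs, DESeq2 gave 2406 higher and 3248 lower, and both copies gave 2736 and 3432. The block gave 2687 and 3123 there, and 2984 and 2307 for vein against primed ECs.

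Without the fold minimum the counts went past that range, because every gene with an adjusted p under 0.05 then counts: primitive streak against hPSCs had 6365 higher and 6447 lower, lateral mesoderm against primitive streak 6248 and 5999, artery ECs against lateral mesoderm 5619 and 5752, and primed ECs against lateral mesoderm 5278 and 5194. Primed against artery ECs then had 4165 and 4161, vein against primed ECs 5961 and 6085, and vein against artery ECs 5817 and 6213.

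With 1 library left out, the counts of genes higher and of genes lower ran from 2539 to 2764 and 2910 to 3239 in primitive streak against hPSCs, 2833 to 2966 and 2254 to 2421 in lateral mesoderm against primitive streak, 2396 to 2432 and 2530 to 2583 in artery ECs against lateral mesoderm, and 1841 to 1895 and 2328 to 2402 in primed ECs against lateral mesoderm. They ran from 1108 to 1197 and 1276 to 1330 in primed against artery ECs, 2691 to 2862 and 2225 to 2329 in vein against primed ECs, and 2758 to 2966 and 2571 to 2776 in vein against artery ECs. Where 1 library was then left in a group, it was assumed to vary like the other groups.

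Lists were more dependent on the test. With an estimated correlation the lists called went from 13 to 8 in artery ECs against lateral mesoderm, from 11 to 5 in vein against primed ECs and from 14 to 9 in vein against artery ECs. The cause was not tested. The rotation test fry, which does not compare a list with other genes, called 19 lists in primed against artery ECs and 20 in vein against primed ECs. Over the 121 list tests, the estimated correlation ended 26 calls, the block ended 10 and added 6, and fry added 33. No list called in either of the 2 tests turned its direction. Turns of lists called in neither were not counted, and some occurred, such as definitive endoderm in lateral mesoderm against primitive streak with the block.

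Of 819 results for named genes, 56 changed call under some setting. None that was called in the report or under the setting turned direction, and turns of results called in neither were not counted. DESeq2 ended 9 calls and effective-length offsets ended 6, and 32 results lost their call in at least 1 of the fits without 1 library (59 of 3468 values). A called fold moved by over 1.5 times in 133 of the results, in 86 of them without 1 library. HSPA1B, whose reads are shared with HSPA1A, was called higher in artery ECs than in lateral mesoderm, and its log2 fold change was 0 without artery EC replicate 1. Depth limits genes with few counts, and simulated changes of 1.5-fold, which lie below the fold minimum, were mostly not called.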

Other observations

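The 7 gene lists of this part, put together after values had been seen, were tested together in 33 tests, and the tests of explanations below were also chosen after the results were seen. Other groups of genes were looked at without a test, so these lists are a selection. HOX genes set position along the body axis, and their 4 clusters were tested apart, in 24 tests of which 8 were not called. No test compared one cluster with another. In primitive streak against hPSCs, 10 of 11 HOXA genes (adjusted p 9.2e-08) and all 10 HOXB genes (1.9e-17) were higher. The HOXC list was not called at that step (5 of 7 higher; 0.32), and a day later all 7 were higher in lateral mesoderm than in primitive streak (1.7e-07), where HOXC6 reached 51.4 ± 5.64 TPM (n = 2). In primed ECs against lateral mesoderm, all 11 HOXA genes were lower (3.0e-12), with HOXA7 at 1.32 ± 0.0791 against 46.1 ± 2.84 TPM, and all 7 HOXC genes were lower (2.2e-07). These calls held with an estimated correlation, each at an adjusted p of 0.036. Every HOXC gene was at 0.566 TPM or less in primitive streak.

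Artery ECs also had lower HOXA genes (9 of 11; 2.3e-06; adjusted p = 0.036 with an estimated correlation) and HOXC genes (5 of 7; 4.0e-05; adjusted p = 0.042 with an estimated correlation) than lateral mesoderm. The HOXB list was lower in primed ECs than in lateral mesoderm (7 of 10 lower; 0.00046; adjusted p = 0.14 with an estimated correlation), yet HOXB9 stayed abundant, at 116 ± 1.71 against 263 ± 4.54 TPM. HOXD genes were lower in primed than in artery ECs (7 of 8; 6.7e-05; adjusted p = 0.051 with an estimated correlation), with HOXD1 at 0.865 ± 0.0148 against 20.2 ± 2.97 TPM. HOXD3, HOXD4, HOXD10, HOXD11 and HOXD13 were at 0.444 TPM or less in artery ECs and lower in primed ECs. Apart from HOXD1, the 8 HOXD genes tested were at 1.59 TPM or less in primitive streak and 3.09 TPM or less in lateral mesoderm. Other HOX calls were also lost with an estimated correlation. All 8 HOXD genes were higher in primitive streak than in hPSCs (0.0076; adjusted p = 0.11 with an estimated correlation) and all 8 lower in primed ECs than in lateral mesoderm (0.00019; adjusted p = 0.062 with an estimated correlation). HOXA genes were higher in lateral mesoderm than in primitive streak (7 of 11, 2 lower; 0.028; adjusted p = 0.31 with an estimated correlation), as were HOXB genes (7 of 10, 1 lower; 9.2e-08; adjusted p = 0.051 with an estimated correlation). HOXA genes were lower in primed than in artery ECs (7 of 11; 0.021; adjusted p = 0.29 with an estimated correlation) and higher in vein than in primed ECs (7 of 11; 0.025; adjusted p = 0.29 with an estimated correlation), and HOXB genes were lower in primed than in artery ECs (4 of 10, 1 higher; 0.022; adjusted p = 0.31 with an estimated correlation). Targets of the aryl hydrocarbon receptor, which senses small aromatic ligands, were higher in primed than in artery ECs. Without CYP1A1, the gene that prompted the list, 2 of 6 tested genes were higher and none lower (0.00083; adjusted p = 0.036 with an estimated correlation), with CYP1B1 at 2.58 ± 0.117 and AHRR at 1.56 ± 0.142. With CYP1A1 (3.19 ± 0.115) it was 3 of 7 (2.1e-07; adjusted p = 0.028 with an estimated correlation). CYP1B1 was lower in both EC groups, at 7.65 TPM in primed and 1.06 TPM in artery ECs, than in lateral mesoderm (37.7 TPM). AHRR was 3.69 TPM in primed ECs, 1.15 TPM in artery ECs and 0.514 TPM in lateral mesoderm. The list without CYP1A1 was not called in vein against primed ECs (1 higher, 1 lower of 6; 0.8), and in vein against artery ECs 2 of 6 were higher (0.032; adjusted p = 0.11 with an estimated correlation). With CYP1A1 these were 0.24, not called, and 0.00011 (3 of 7 higher; adjusted p = 0.032 with an estimated correlation). Interferon-stimulated genes were higher in vein than in artery ECs (14 of 23 higher, none lower; 0.0064; adjusted p = 0.046 with an estimated correlation) and in vein than in primed ECs (11 of 23 higher, none lower; 0.0067; adjusted p = 0.055 with an estimated correlation), with IFIT1 at 2.29 against 0.217 TPM in primed ECs. They were not called in primed against artery ECs (5 of 23 higher, 1 lower; 0.57). A list of p53 target and arrest genes was not called in vein against primed ECs (4 of 19 higher, 1 lower; 0.12), in primed against artery ECs (1 higher, 2 lower; 0.8) or in vein against artery ECs (5 higher, 3 lower; 0.19). With CDKN1A and ZMAT3, which had prompted it, it had 5 higher and 1 lower of 21 in vein against primed ECs (0.021; adjusted p = 0.11 with an estimated correlation), 7 higher and 3 lower in vein against artery ECs (0.024; adjusted p = 0.11 with an estimated correlation), and no call in primed against artery ECs (0.85). In vein against primed ECs ZMAT3 was higher by 2.96 ± 0.116, and CDKN1A (0.77, adjusted p 3.9e-07) missed the fold minimum and was not called. Both were called in vein against artery ECs, ZMAT3 at 3.59 ± 0.122 and CDKN1A at 1.45 ± 0.0783. Neither was called in primed against artery ECs (0.63 and 0.69).

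Of the 23 ERK targets, 8 had over 2 times the TPM in vein EC replicate 1 that they had in replicate 2, and 1 was the other way. Of the 8, DUSP4, SPRED2, ETV1, EGR1 and EGR3 were below 1 TPM in both vein EC libraries, as was KCNN4, the gene that went the other way. No ERK target differed by that much between the primed EC libraries, where all 8 were more abundant. Other genes of similar level were not compared, and no test was made of these counts. DUSP6 was 3.76 TPM in replicate 1 and 1.24 TPM in replicate 2, SPRY4 was 2.16 and 0.441 TPM, and ETV5 was 1.34 and 0.119 TPM. Primed ECs had 193 TPM of DUSP6 in each library.

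Vein ECs had more COL1A2, at 838 against 140 TPM in primed ECs (2.33 ± 0.0914), and more ACTA2, at 234 ± 0.768 against 62.7 ± 0.582 TPM (1.72 ± 0.107). If mesenchymal or smooth muscle cells had come through the CD144 sort, 7 other abundant genes of such cells should have gained with COL1A2. Their summed gain was 1.06% of that of COL1A2 (7.43 against 698 TPM). This sum is net of the fall of TAGLN, so it understates the gains of the genes that rose. COL1A1 was 1.80% of COL1A2 in vein ECs against 65.6% in lateral mesoderm, which argues against cells rich in COL1A1 as the whole source. Of the 7 genes, COL3A1 (3.88), LUM (4.70) and POSTN (6.67) were called higher, COL3A1 to 19.99 TPM and the others to less. POSTN had 3 counts in primed ECs (ratio 112, 95% interval 37.9 to 544), and was at 10.09 and 5.99 without primed EC replicates 1 and 2 in turn. TAGLN (-1.08) was called lower, and COL1A1 (0.18), DCN (0.73) and PDGFRB (-0.04) were not called. Outside the 7, FN1 rose with COL1A2, from 191 ± 0.148 to 1360 ± 14.4 TPM (2.60 ± 0.133), and VIM from 2430 ± 62.0 to 6920 ± 10.2 TPM (1.32 ± 0.0951), as mesenchymal cells would need. Transcript length is argued against too, since the lower log2 fold change of the 2 genes was 1.67 with effective-length offsets. Library scaling was not tested for them. Expression by the ECs themselves and a cell type low in COL1A1 and TAGLN both stay open.

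The 40 cell-cycle genes were all lower in vein than in primed ECs. Library scaling alone is argued against, since a factor of a library moves all genes alike and the median log2 fold change of these genes minus that of all tested genes was -3.14. The vein step and the extra day of culture cannot be told apart, because 1 group alone was of day 4 and no primed ECs kept until then were analysed here. Lower expression of these genes in vein ECs is thus open as an effect of either. Only transcripts were measured here, so proliferation itself was not tested.

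Dissociation stress and immediate-early genes were lower in 15 of 18 cases in vein against primed ECs (adjusted p 6.3e-12, or 0.09 and not called with an estimated correlation). Were lower expression of ERK targets alone the cause, 4 chaperone genes that are in no ERK list should not have fallen. Their median was -1.31, with 3 of them called lower. The 4 are members of the stress list and were chosen after its fall was seen, so their fall is no separate evidence. Genes outside the ERK list were also not shown to be independent of ERK, so the chaperones cannot decide the question. The stress and ERK lists share 1 tested gene, EGR1. The 14 of 17 stress genes outside the ERK list that were lower therefore restate the fall of the stress list. More handling stress in the sorted primed ECs and a change with the vein step cannot be told apart. The median of the stress list was 0.11 in primed ECs against unsorted lateral mesoderm, with members going both ways and no call. In primed against artery ECs its median was -0.02 (4 higher, 5 lower, no call), and in vein against artery ECs -2.24. The list as a whole was thus not seen higher in primed than in artery ECs. Handling shared by both groups of day 3 was not tested. In primed against artery ECs, which had the same sort, 3 of the 4 chaperone genes were called higher, HSPH1 at 1.75 ± 0.0739, HSPA8 at 1.34 ± 0.0763 and HSP90AA1 at 1.24 ± 0.0864, and DNAJB1 (0.76) was not. In vein against artery ECs none of the 4 was called (HSP90AA1 -0.62, HSPA8 0.91, DNAJB1 -0.36, HSPH1 0.24). They missed the fold minimum alone, with adjusted p from 4.2e-08 to 8.1e-03, and their changes went both ways. There 12 of 18 stress genes were lower and 1 higher (adjusted p 5.9e-09, or 0.11 with an estimated correlation). The 4 chaperones were among the members of the list that were not called.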
